A study of Mus musculus with 10 samples.

How the data were processed

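RNA was measured on 10 single-colour Agilent microarrays, 1 array per sample. Per the labels, adult female C57BL/6J mice, an inbred laboratory strain, breathed either ethanol vapor or room air for 8 h a day on 5 days a week over 4 weeks, and whole brains were taken right after the last day of exposure. Extracellular vesicles, the membrane-bound particles that cells release, were isolated from the brains by differential ultracentrifugation, and about 3 µg of total RNA per sample was purified with a SeraMir kit, amplified and labelled with Cy3. Groups were taken from the sample titles, which gave 5 arrays of room air and 5 of ethanol vapor. Replicates carry the sample numbers of the titles, which run across both groups, so no number is shared and no samples were paired. The labels do not say that each sample came from a separate animal, so p-values measure the spread between these samples, which may be partly technical. No 2 arrays held identical values (highest share of equal values 0%).

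The deposited scanner files hold spot intensities on a linear scale, made with Agilent Feature Extraction 11.0.1.1, per the file headers. The processed intensity used here is background-subtracted and detrended within each array and is not scaled between arrays, per the file headers. The authors' deposited value table holds 60641 probes on a log2 scale, as found by setting each column against the log2 processed intensity of its own array (lowest r 0.993). Its columns share nearly the same quantiles, with medians of 6.50 in every array, and how it was made is not given in the sources used here. It holds no centring on genes, gives levels and not ratios, and was used as an alternative.

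Each array has 62976 spots, of which 61537 are not controls and represent 60823 probes. No spot was saturated. Control spots and spots marked as non-uniform were left out. The log2 processed intensity was reduced by the 75th percentile of each array over all spots that are not controls, since on the median array 77.9% of them were well above background. Spots of a probe were averaged. Probes were tested where they were well above background on at least 5 of the 10 arrays, whatever the group, which kept 49363 and left out 11460. A probe printed several times counted as above background on an array where at least 0.5 of its spots were.

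The arrays fall into 2 sets that share the identifier of their scan image in the file headers. Each set is called a slide here, although the identifier may also stand for a scan or a hybridisation day. Slide 1 holds 3 room air arrays and 1 ethanol array, and slide 2 holds 2 room air arrays and 4 ethanol arrays. The labels name no slide, so the fit fixed before the data were examined has no slide term, and the slide as a fixed block was one of its alternatives. Because both slides hold both groups, blocked and within-slide values stand beside the results.

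Gene names came from the accessions in the files through a RefSeq gene table of assembly GRCm38.p6. Only 50 probes, each printed at 10 spots, carry an accession that could be looked up, and 46 of them matched a symbol, 45 of protein-coding genes and 1 of a transcribed pseudogene. The array headers name the build mm9, so no coordinates are given. Other probes carry names of the array maker alone and have no gene name here. Probes were classed as messenger RNA by accession or coding biotype (34 tested), as noncoding by a probe name that contains LNC or lincRNA or by accession (24545 tested), and otherwise left unclassified (24784 tested). The class of the unclassified probes is not given in the sources used here.

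Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Values of a single measure per array were compared with exact permutation tests over all 252 splits into groups of 5, two-sided, and over the 60 splits that keep the number of ethanol arrays on each slide. The 27 gene lists, with 514 genes, needed at least 5 tested members for a set test, and none had them, so no set test was run. The named genes were fixed by a rule before the data were examined. Since no gene passed the threshold, the rule took the 10 genes with the smallest p in each direction and up to 3 members of each list, 21 genes in all, of which 1 is not reported here. Noncoding probes without a gene name are given by probe name, at most 2 in each direction.

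The fits were tested on simulated data with the measured probe means and slide differences, in 5 runs over 49028 probes with 200 probes changed per fold size. The spread of each probe was drawn at random from the distribution of variances that limma fitted. Noise was independent between probes, which real arrays need not follow, so the shares below hold for idealised data. Without a slide term 0.7% of 2-fold changes and 40.0% of 4-fold changes were recovered. With the slide as a block the shares were 49.4% and 94.7%, and 4.1% of 1.5-fold changes were recovered. The number of arrays limits the precision.

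Alternatives covered the background correction and scaling (normexp with an offset of 50 and quantile normalization, quantile normalization alone, median scaling, the 75th percentile over probes above background on all arrays, the authors' table), the filter on dim probes, outlier spots, the slide, a trended and robust variance, array weights, an unadjusted threshold with 1.5-fold change, and leaving out each array. The normexp alternative used the median spot signal, since the files carry no mean spot signal. Figures were drawn with matplotlib 3.10.9.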

Results

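The RNA carried by extracellular vesicles of the brain was profiled in female mice after 4 weeks of intermittent ethanol vapor (5 arrays) and after room air (5 arrays). The comparison asked which messenger and long noncoding RNAs of the vesicles differ after chronic ethanol exposure. Between 62.1% and 87.9% of the spots that are not controls were well above background on an array. Levels are log2 intensities relative to the 75th percentile of the array, and differences are ethanol vapor minus room air. Of the 46 probes with a gene name, 35 were measured well enough to be tested. Whether each probe reports its named gene was not tested. In room air the probes of Pex11a (3.74), Duox1 (3.13) and Il2 (2.98) read above those of Actb (0.98) and Mbp (1.17). Levels are therefore those of probes, and are not read as RNA amounts between genes.

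Pex11a, which encodes a membrane protein that promotes peroxisome division, had the smallest p of the named genes. Its level was 3.74 ± 0.86 (SD, n = 5) in room air vesicles and 4.98 ± 0.42 (SD, n = 5) in ethanol vesicles, a difference of 1.24 (SE 0.40) or 2.36-fold. The adjusted p was 0.527 in the limma fit, so Pex11a did not pass the threshold, nor did it when adjusted over the list alone (0.366). When the slide was a block, the Pex11a difference was 0.82 (SE 0.28, 95% interval 0.22 to 1.43) with an adjusted p of 0.577. It was 1.35 on slide 1, where the ethanol group had 1 array, and 0.53 on slide 2. The ranges of the groups overlapped for Pex11a, with room air arrays from 2.90 to 4.92 and ethanol arrays from 4.54 to 5.50.

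The other 9 genes with the smallest p among those with a higher mean after ethanol did not pass the threshold either. Atg3, an enzyme that attaches lipid to LC3 proteins in autophagy, averaged -4.30 ± 1.51 (SD, n = 5) in room air and -3.14 ± 1.21 (SD, n = 5) in ethanol vesicles. Its difference of 1.15 (SE 0.76) shrank to 0.10 (SE 0.25) with the slide as a block. The Atg3 probe was well above background on 2 of 5 room air and 3 of 5 ethanol arrays. Nup50, a nuclear pore protein that was well above background on 2 of 5 room air and 4 of 5 ethanol arrays, differed by 0.84 (SE 0.45) and by 0.23 (SE 0.16) with the block. Alkbh4, a demethylase, differed by 0.80 (SE 0.53), and the blocked value was 0.083 (SE 0.20). For the class I histocompatibility gene H2-Q7 the values were 0.74 (SE 0.48) and 0.10 (SE 0.17). Alkbh4 and H2-Q7 were well above background on 3 of 5 room air and 4 of 5 ethanol arrays, and Lhfp on 3 of 5 arrays of each group. On slide 1 Atg3 and Nup50 were so on 0 of 4 arrays. Dim readings enter the differences of Atg3, Nup50, Alkbh4, H2-Q7 and Lhfp, so their sizes are uncertain. On every array Atg3 read below the median of the noncontrol probes that carry a name of negatives, and Lhfp did so on every slide 2 array. Gsta4, a glutathione transferase that detoxifies products of lipid peroxidation, differed by 0.64 (SE 0.37) and, blocked, by 0.17 (SE 0.17). Rps4l, a transcribed ribosomal protein pseudogene, differed by 0.52 (SE 0.33) and 0.14 (SE 0.18). The remaining members were Lhfp, Acaa2, a thiolase of mitochondrial fatty acid oxidation, and Hyal3, a hyaluronidase family gene, with differences of 0.45, 0.43 and 0.34 and blocked values of 0.091, 0.098 and 0.18. All 10 genes, Pex11a included, had a smaller difference with the block than without it. The signs of Lhfp and Acaa2 turned with quantile normalization. Median scaling moved the difference of every named gene by the same -0.43, which took Hyal3 and Acaa2 below 0.

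Among the genes with a lower mean after ethanol, Gm9789 had the smallest p, with 1.06 ± 0.18 (SD, n = 5) in room air and 0.63 ± 0.39 (SD, n = 5) in ethanol vesicles. Its difference was -0.43 (SE 0.23), and -0.31 (SE 0.20) with the slide as a block. Duox1, an oxidase that produces hydrogen peroxide, had the lowest difference of the 20 named genes, -1.07 (SE 0.61), against -0.23 (SE 0.17) with the block. Il2, the T cell growth factor interleukin 2, differed by -0.88 (SE 0.68), and Gsdmd, the pore-forming gasdermin of pyroptosis, by -0.86 (SE 0.66). With the block the Il2 and Gsdmd values changed sign, to 0.064 (SE 0.19) and 0.072 (SE 0.16). Chgb, the secretory granule protein chromogranin B, also changed sign, from -0.36 (SE 0.31) to 0.0085 (SE 0.15). Gamt, which completes creatine synthesis, differed by -0.46 (SE 0.34) and -0.041 (SE 0.16). The olfactory receptor gene Olfr166 differed by -0.26 (SE 0.18) and -0.18 (SE 0.13), and the histocompatibility gene H2-M2 by -0.21 (SE 0.17) and -0.19 (SE 0.13). Olfr166 was the 1 gene of 35 whose groups did not overlap, with 0.988 to 1.34 in room air and 0.77 to 0.975 in ethanol arrays. The median SD between its printed spots was 0.095. Chance would separate the groups in 0.794% of genes if all arrays were exchangeable. With 23 of the 35 genes past the threshold between slides they were not, so that share is not read as a chance level. The Actb (beta-actin) difference was -0.075 (SE 0.19), and -0.067 (SE 0.16) when blocked. The differences of Actb and H2-M2 turned positive with quantile normalization. Taking the 75th percentile over probes above background on all arrays moved every named gene by the same 0.26, which took Actb, H2-M2, Olfr166 and Mbp above 0.

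**Figure D1:**
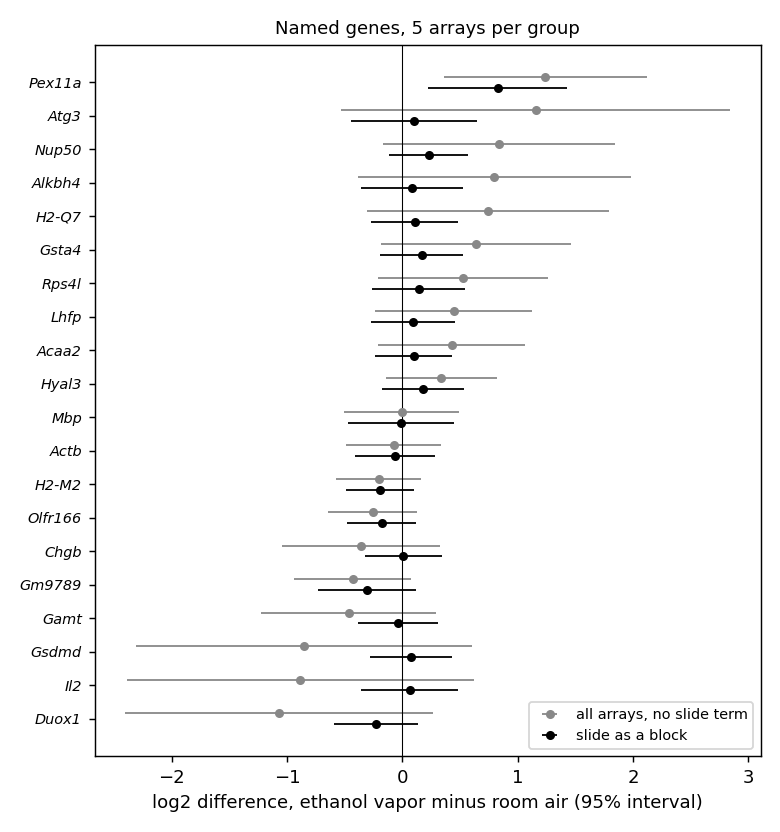
Log2 differences of the 20 named genes, ethanol vapor minus room air, with 95% confidence intervals from limma. Grey points are the fit of all 10 arrays without a slide term and black points the fit with the slide as a block, and of the black intervals that of Pex11a (0.22 to 1.43) lies above 0.

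Of the 35 named and tested genes, 23 had a higher and 12 a lower mean after ethanol. These counts depended on the scaling and the slide, with 10 and 25 after median scaling, 16 and 19 after quantile normalization, 28 and 7 with the percentile over probes above background on all arrays, and 21 and 14 with the slide as a block. In limma 0 of them passed the adjusted threshold, over all probes or adjusted over the list alone, and 1, Pex11a, had an unadjusted p under 0.05. In the blocked fit 0 passed and 4 had an unadjusted p under 0.05. Besides Pex11a these were Lhx1, a homeobox transcription factor, Tm9sf1 and the olfactory receptor gene Olfr1307, with blocked differences of -0.66 (SE 0.23), -0.59 (SE 0.27) and -0.47 (SE 0.21). These 3 genes fall outside the naming rule and were chosen after their values were seen. The 2 fits gave opposite signs for 10 of the 35 genes, Lhx1, Tm9sf1 and Olfr1307 among them. For 32 genes the blocked 95% interval lay within a 2-fold change in either direction.

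**Figure D2:**
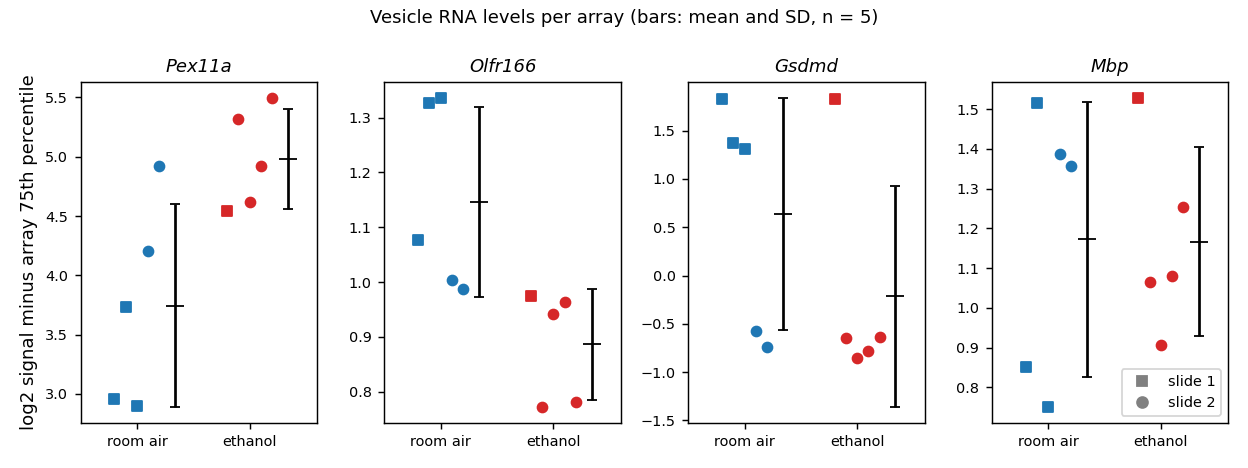
Level of Pex11a, Olfr166, Gsdmd and Mbp on each array, in log2 intensity relative to the 75th percentile of the array, for room air and ethanol vapor, with squares for slide 1 and circles for slide 2 and bars for the mean and SD (n = 5). Gsdmd follows the slide in both groups, and the Pex11a ethanol arrays run from 4.54 to 5.50.

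Mbp, which encodes myelin basic protein, was the only member of the planned gene lists that had a named and tested probe. Its level was 1.17 ± 0.35 (SD, n = 5) in room air and 1.17 ± 0.24 (SD, n = 5) in ethanol vesicles, a difference of -0.0053 (SE 0.23), and -0.013 (SE 0.21) with the slide as a block. The Mbp difference was 0.49 on slide 1 and -0.30 on slide 2. The GABA receptor gene Gabrg1 had a named probe that was too dim to test. The other lists, of neuron, glia, vascular, blood and meningeal markers, vesicle biogenesis, immune, ethanol metabolism, synaptic, stress, ribosomal, mitochondrial, sterol, clock, chromatin and known noncoding genes, had no named probe among the 35 genes, and 0 lists could be tested as a set.

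Long noncoding RNAs were represented by 24545 tested probes classed as noncoding. These include 714 probes named as human lincRNAs and the pseudogene probe of Rps4l. Of the 24545 probes, 0 passed the adjusted threshold in limma and 1240 had an unadjusted p under 0.05. Evenly spread p-values would give 1227, which need not be the chance level for these arrays. With 1 array left out the count reached 9583, and it was 519 without room air replicate 2. In the blocked fit 0 noncoding probes passed and 2128 had an unadjusted p under 0.05. The noncoding probe ASMM10LNC1A103142802V4 had a difference of 2.51 (SE 0.49), and ASMM10LNC1A100063878V4 one of 2.58 (SE 0.51). Both were well above background on 1 of 5 room air arrays, against 4 and 5 of 5 ethanol arrays, so their room air levels are mostly dim readings and the sizes of the differences are uncertain. Their blocked differences were 2.49 (SE 0.51) and 2.18 (SE 0.44). ASMM10LNC1A111808057V4 and ASMM10LNC1A104338814V4 were lower, with differences of -0.75 (SE 0.23) and -0.65 (SE 0.20) and blocked differences of -0.83 (SE 0.21) and -0.67 (SE 0.18). ASMM10LNC1A111808057V4 was well above background on 5 of 5 room air arrays but on 1 of 5 ethanol arrays, so the size of its difference is uncertain as well. The adjusted p of all 4 was 0.527, and 0.577 with the block. Of the messenger RNA probes with an accession, 0 of 34 passed and 1, that of Pex11a, had an unadjusted p under 0.05.

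Over all classes 0 of 49363 probes passed the adjusted threshold in limma, with a smallest adjusted p of 0.527. An unadjusted p under 0.05 was found for 2485 probes, 2288 higher and 197 lower in ethanol vesicles. Evenly spread p-values would give 2468, but other splits of the arrays gave from 11 to 32768. So 2468 is not read as a chance level. With a 1.5-fold change added, the real groups gave 2187 and other splits a median of 530. Of 100 splits, 15, the real one included, reached 2187. With 1 array left out the count of 2485 ran from 605 to 18959. The balance of higher and lower probes depended on the scaling. It was 1096 higher and 2002 lower after median scaling, and 2505 and 1383 after quantile normalization. With the percentile over probes above background on all arrays it was 3302 and 20. With the slide as a block 0 probes passed (smallest adjusted p 0.410), and 4242 had an unadjusted p under 0.05, 1996 higher and 2246 lower. The blocked counts were 1222 higher and 3127 lower after median scaling, 1909 and 2493 after quantile normalization, and 3340 and 1112 with the percentile over probes above background on all arrays. Within slide 2 alone 0 probes passed, with a smallest adjusted p of 0.145. Slide 1 alone also gave 0 (smallest adjusted p 0.435), but it holds 1 ethanol array, assumed there to vary like the 3 room air arrays, so that count says little. The median difference over all probes was 0.26, and 0.037 with the slide as a block. Without the block it was 0.018 after quantile normalization, -0.17 after median scaling and 0.52 with the percentile over probes above background on all arrays (0.11 with the block). With array weights in the fit 34856 probes passed, and with array weights and the slide block 0 did, with 8042 at an unadjusted p under 0.05. The 95% interval of the difference lay within 2-fold for 38.3% of probes, and for 86.7% with the slide as a block.

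The balance of noncoding and messenger RNA did not differ between groups beyond the spread between arrays. The mean noncoding level minus the mean messenger level was -0.011 ± 0.14 (SD, n = 5) in room air and 0.13 ± 0.14 (SD, n = 5) in ethanol vesicles, with an exact permutation p of 0.135 (0.397 adjusted over 4 measures). With the slide as a block the difference of 0.14 became 0.030 (exact p 0.367 within slides), with -0.020 on slide 1 and 0.059 on slide 2. Without ethanol replicate 4, the ethanol array on slide 1, it was 0.20 (exact p 0.0317). The remaining ethanol arrays are all on slide 2, where this measure was 0.28 higher than on slide 1 (exact permutation p 0.0048). The messenger mean rests on 34 probes. The share of spots well above background was 75.7% ± 9.47 (SD, n = 5) in room air and 77.6% ± 9.50 (SD, n = 5) in ethanol vesicles, with an exact permutation p of 0.770. Within slides the direction was the other way, with differences of -7.28 percentage points on slide 1 and -3.78 on slide 2, and -5.04 with the slide as a block (exact p 0.117).

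The largest axis of variation followed the slides. The first principal component held 81.2% of the variance and separated the 4 arrays of slide 1 from the 6 of slide 2 (exact permutation p 0.0048, the smallest that its 210 splits allow). The groups differed on it by 126 (exact permutation p 0.198), and by 6.82 with the slide as a block (exact p 0.6). Arrays of one slide correlated across probes with a mean r of 0.981 within a group and 0.982 between groups, against 0.911 and 0.904 for arrays of different slides. Between the slides 37037 of 49363 probes passed the threshold, 27877 higher on slide 2 and 9160 lower. Of the named genes, 23 of 35 passed between slides. For 32 the group difference had the sign of the slide difference, and for 22 with the slide as a block. The uneven spread of the groups over the slides can give such agreement without any ethanol effect. Il2, Gsdmd and Duox1 were lower on slide 2, with slide differences of -2.37, -2.32 and -2.11. Atg3 was well above background on 0 of 4 arrays of slide 1 and 5 of 6 of slide 2. On slide 2 it averaged -2.70 in room air and -2.62 in ethanol arrays. The median of the noncontrol probes that carry a name of negatives ran there from -2.38 to -1.76, and Atg3 was below it on each array. Its passing the background is therefore not read as detection of the transcript.

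**Figure D3:**
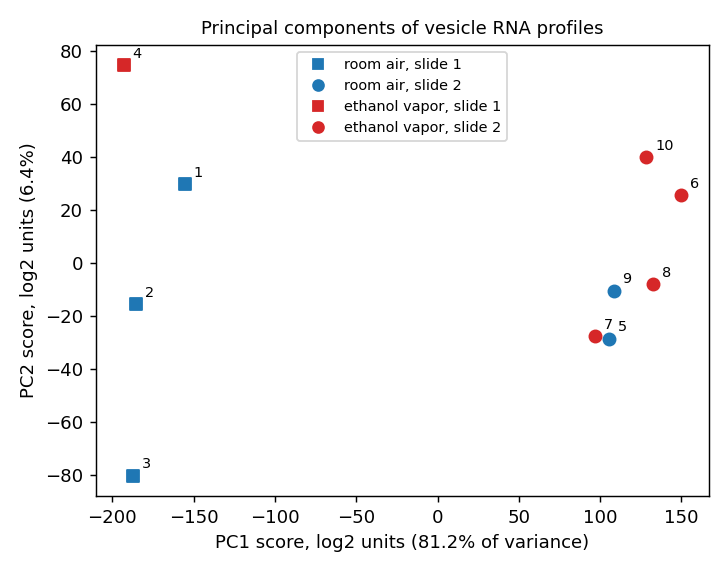
Scores of the 10 arrays on the first 2 principal components of the tested probes, in log2 units, coloured by group, with squares for slide 1 and circles for slide 2 and the replicate number beside each point. The first component (81.2% of variance) separates the slides, and each slide holds both groups.

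Control probes differed between the slides as well. E1A control probes, which are not directed at mouse genes, were well above background for 41.7% to 50.6% of spots on slide 1 and 85.1% to 91.1% on slide 2. Noncontrol probes that carry a name of negatives were so for 17.8% to 31.1% of spots on slide 1 and 55.6% to 82.2% on slide 2. Structural negative spots stayed at or below 2.27% on every array.

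**Figure D4:**
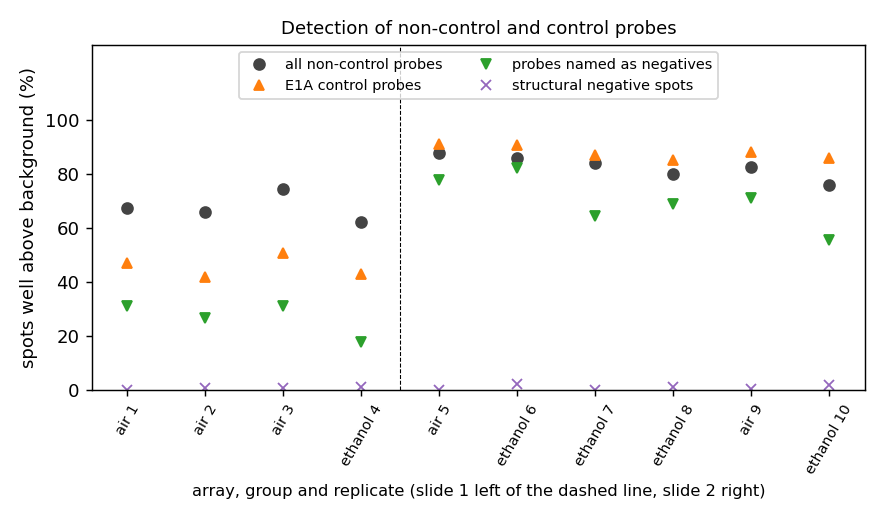
Percent of spots well above background on each array for all non-control probes, E1A control probes, probes named as negatives and structural negative spots, with slide 1 left and slide 2 right of the dashed line. E1A control probes lie between 41.7% and 50.6% on slide 1 and between 85.1% and 91.1% on slide 2.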

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

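The tests of the slides, the array weights and the interval were chosen after the results were seen. The counts over other splits of the arrays were fixed before those splits were run.

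In 11 of 48 groups of 5 values, 1 array lay far from the others, and in all 11 it was ethanol replicate 4, the only ethanol array on slide 1. Chance marks about 1 group in 20, or 2.4 of 48 if the groups were independent. They share the same 10 arrays and many follow the slide, so 2.4 is not read as a chance level. The gap to the nearest array was 0.922 of the whole ethanol range for Gsdmd, 0.843 for Gamt, 0.807 for Duox1, 0.787 for Il2 and 0.773 for Chgb, all with the lone array highest. It was 0.781 for Nup50, 0.734 for Alkbh4 and 0.728 for Atg3, with the lone array lowest. It was 0.862 for the noncoding minus messenger level, 0.789 for the difference between the probe families ASMM10LNC1A and ASMM10AP1B, and 0.847 for the first principal component. The Gsdmd level of this array was 1.83, beside -0.85 to -0.64 on the other ethanol arrays, and the highest room air array, also on slide 1, was at 1.83.

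Most probes differed between the slides (37037 of 49363). A different mix of mouse RNA in the samples, taken alone, predicts equal E1A control signal on both slides. That holds only if the E1A signal does not depend on the RNA hybridised, which was not tested. The median log2 E1A signal was 1.80 higher on slide 2, with an SD of 0.17 between arrays of a slide. The median signal of probes named as negatives rose too, from a mean of 13.4 on slide 1 to 63.8 on slide 2. The E1A probes therefore cannot decide, and this explanation stays open. A compressed signal range on one slide that keeps the order of the probes, taken alone, is argued against by quantile normalization, after which 27485 probes still passed between slides. A compression that reorders dim probes would survive that step and stays open. The median signal of non-control spots averaged 65.0 on slide 1 and 114 on slide 2, and the 75th percentile 301 and 277. Different batches of animals or RNA preparations on the 2 slides stay open, since 0 samples were hybridised on both slides, and cannot be told apart from the hybridisation itself. No biological explanation was tested, as the design names none for the slide.

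With array weights 34856 probes passed between the groups, against 0 without weights. A candidate explanation is that the weights turned the group contrast into the slide contrast. Of the called probes, 99.6% had the sign of the slide difference, and the 3 arrays on the slide where their group is in the minority (ethanol replicate 4, room air replicates 5 and 9) together kept 3.35% of the weight. An ethanol response of the called size that low-quality arrays hide is argued against by the weighted fit with the slide as a block, whose 95% interval left out the called difference for 94.0% of the called probes (median size 1.23 as called and 0.19 with the block). In that fit 0 probes passed (smallest adjusted p 0.151), but 8042 had an unadjusted p under 0.05, against 4242 in the blocked fit without weights. Evenly spread p-values would give 2468. Of the 60 splits within slides, with weights estimated anew, 17 reached 8042, the real one included, with 16111 as the highest other, so chance cannot be excluded. In 9 of these splits, though not in the real one, probes passed the adjusted threshold, up to 6364. Without weights 1 of the 60 splits gave any call, of 1 probe. No test here separates a structure of the samples within the slides from an effect of the weights themselves. A smaller ethanol response that low-quality arrays hide stays open.

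No probe passed between the groups in limma without weights (2485 at an unadjusted p under 0.05). That the slide difference hides intensity differences of 2-fold or more in most probes is argued against by the blocked fit. Its 95% interval lay within 2-fold for 86.7% of probes. Smaller changes, and changes in the other probes, stay open. The intervals bound intensities and not RNA amounts. On slide 2 the median signal of probes named as negatives averaged 63.8 over the arrays, against 114 for all non-control spots. RNA differences of 2-fold or more therefore stay open as well. No split can give fewer than the real count of 0, so counting splits (100 of 100 gave at least as many, with 30186 as the highest other) decides nothing about chance here. The 4 splits that put all slide 1 arrays in one group gave 24849 probes or more, which points to the slide as the structure of these samples, and the other 96 gave 0. For probes with an unadjusted p under 0.05 and a 1.5-fold change, 15 of 100 splits, the real one included, reached the real 2187, with 29808 as the highest other, so chance cannot be excluded. With the slide as a block, 8 of the 60 splits within slides, the real one included, reached the real 4242 probes at an unadjusted p under 0.05, with 11609 as the highest other, so chance cannot be excluded there either.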

How the results depend on the processing

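Chosen after seeing the data were each slide alone, the filter on control probe brightness, the probe family contrast, the slide block for the 3 measures with 1 value per array, and the slide block combined with other scalings, array weights, the unadjusted threshold, that filter, that contrast or the loss of ethanol replicate 4. The count of probes past the threshold stayed at 0 in 29 of 32 alternatives, among them every scaling, the authors' table, every filter, the slide block, slide 2 alone and each array left out. Slide 1 alone, with 1 ethanol array, is among the 29 but says little. The exceptions were array weights (34856 probes, 26709 higher and 8147 lower, with 23 messenger and 17416 noncoding probes), where the slide sign of 99.6% of the calls bears on the cause, and the unadjusted p under 0.05 with a 1.5-fold change, which by its construction counts 2187 probes (1 messenger, 1104 noncoding) and with the slide block 1827 (3 messenger, 893 noncoding). Array weights with the slide block gave 0, but 8042 at an unadjusted p under 0.05, against 4242 with the block alone. Leaving out ethanol replicate 4 gave 0 probes but 18959 at an unadjusted p under 0.05, against 2485 with all arrays. With the slide as a block the same arrays gave 0 and 2081, and without a block but without room air replicate 9 or 5 there were 7628 and 6514. Without room air replicate 1, 2 or 3 there were 1061, 1061 and 605, and without ethanol replicate 6, 7, 8 or 10 there were 697, 1927, 1045 and 747.

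The noncoding minus messenger level kept its direction in 20 of 21 alternatives and ran from 0.093 to 0.20 with an array left out. It passed the threshold without ethanol replicate 4 (0.20, exact permutation p 0.0317), and the smallest p of its alternatives is that one. All ethanol arrays then lie on slide 2, where the measure was 0.28 higher than on slide 1 (exact permutation p 0.0048). That result therefore cannot be told apart from the slide. With the ASMM10LNC1A minus ASMM10AP1B probe families in its place, the group difference was 0.012. This family difference turned to -0.016 with the slide block (-0.025 on slide 1, -0.010 on slide 2). The first-component separation kept its side of the threshold in 20 of 20. Its sign is arbitrary. The share of spots well above background turned to -5.04 percentage points with the slide block and ran from -0.518 to 5.77 with an array left out. The cause of these moves of the share was not tested.

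The 20 named genes had 533 values under alternatives, of which 17 passed, all with array weights, and 45, in 14 genes, had the other sign. With the slide block these were Gsdmd 0.072, Chgb 0.0085 and Il2 0.064. With quantile normalization they were Actb 0.11, H2-M2 0.0012, Mbp 0.19, Acaa2 -0.13 and Lhfp -0.18, and with normexp and quantile normalization Actb 0.10, H2-M2 0.0064, Mbp 0.16, Acaa2 -0.049 and Lhfp -0.062. Median scaling gave Hyal3 -0.091 and Acaa2 -0.0017. The percentile over probes above background on all arrays gave Actb 0.19, H2-M2 0.054, Olfr166 0.0023 and Mbp 0.26. Array weights gave Mbp 0.0080. On slide 1 alone the values were Actb 0.075, Gamt 0.27, Hyal3 -0.087, Gsdmd 0.33, Chgb 0.31, Alkbh4 -0.057, Mbp 0.49, Duox1 0.083 and Il2 0.24. The slide block with quantile normalization gave Mbp 0.030, Acaa2 -0.0049, Il2 0.10 and Atg3 -0.12, and with normexp as well Gsdmd 0.00064, Mbp 0.0098 and Il2 0.11. The slide block with array weights gave Gsdmd 0.028 and Il2 0.033, and the slide block on probes brighter than control probes gave Il2 0.064. Mbp ran from -0.11 to 0.080 with an array left out. Of the 20 genes, 10 moved by over 1.5 times with some array left out, 7 of them farthest without ethanol replicate 4. Il2 ran from -1.39 to -0.56, Gsdmd from -1.37 to -0.56, Gamt from -0.73 to -0.32, Chgb from -0.60 to -0.25, Atg3 from 0.72 to 1.68, Alkbh4 from 0.51 to 1.18, Lhfp from 0.28 to 0.62, Rps4l from 0.35 to 0.71 and Actb from -0.15 to -0.013. The 6 turns with median scaling and with that percentile come from a common move of every named gene, by -0.43 and 0.26. The cause of the other 39 was not tested. Pex11a kept its direction in 28 of 28 alternatives, and ran from 0.53 to 1.84, with adjusted p from 0.00019 (array weights) to 0.935.

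The authors' table holds no probe with a gene name, so named genes and messenger probes have no value there. Signal over background limits the dim probes: 8 of the 35 named genes were not well above background on every array.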

Other observations

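Genes outside the naming rule with a tested probe included Apoe, the main lipid carrier of the brain. Its probe was at 0.81 ± 0.19 (SD, n = 5) in room air and 0.89 ± 0.063 (SD, n = 5) in ethanol vesicles, with a blocked difference of 0.048 (SE 0.14). Rab5a, a GTPase of early endosomes, differed by 0.41 (SE 0.32) and, with the slide as a block, by 0.010 (SE 0.14). The peroxide-reducing enzyme Prdx2 differed by 0.12 (SE 0.18) and, blocked, by 0.082 (SE 0.14). Anxa8, a calcium-dependent membrane-binding protein, had a blocked difference of 0.36 (SE 0.22). None passed the threshold, and these 4 genes were chosen after their values were seen.

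Probes named as human lincRNAs were well above background for 43.6% to 58.3% of spots on slide 1 and for 57.8% to 75.9% on slide 2, and probes named as mouse lincRNAs for 46.6% to 62.6% and 59.3% to 79.8%. Of the 15 probes named as negatives, 10 passed the filter on dim probes. The filter therefore kept probes that are not directed at mouse transcripts by their names, and its count of 49363 is not a count of transcripts present in the vesicles. When probes had to be brighter than the 95th percentile of the E1A and negative-named probes on at least 5 arrays, 15284 remained, of which 0 passed in limma and 726 had an unadjusted p under 0.05.

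Across the 49363 tested probes, which are not independent replicates, the group difference without a slide term correlated with the slide difference (r 0.850), in a design that spreads the groups unevenly over the slides. For the named genes, 10 printed spots of a probe had a median SD of 0.15 within an array, against a median SD of 0.51 between arrays of a group and a residual SD of 0.21 with the slide as a block.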
